A study of Mus musculus with 4 samples.

How the data were processed

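Ovarian RNA of 4 mice was measured on 4 Affymetrix whole-transcript arrays, 1 for each of 4 groups: the untreated wild type, the wild type 4 h after 5 IU of eCG, the untreated estrogen-deficient (ArKO) mouse, and the ArKO mouse 4 h after 18 mg/kg of estradiol. Per the labels' protocols, RNA was prepared individually from each sample and 100 ng of total RNA was labelled with biotin using the GeneChip WT PLUS kit. The labels disagree on the route of the eCG injection: the protocol says intraperitoneal and the sample description subcutaneous. Estradiol was given subcutaneously. Groups were taken from the sample titles.

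The log2 values were made by the authors with RMA, per the submitters' processing notes, a method that corrects the background, normalizes the arrays to a common distribution and summarises the probes of a row. There is 1 value for each of 41345 rows per array. They were read as log2 because RMA gives log2 values and they run from 0.34 to 13.26; no base is stated with them. Versions and the genome build of the array annotation are not given in the sources used here, so no coordinates are printed. Gene neighbourhoods and biotypes were taken from a gene table of assembly GRCm38.p6. Because RMA evens out the distributions, a difference shared by most transcripts would not be seen, and differences are relative to the other genes of an array.

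Rows were named through the platform annotation of the arrays. It gives 1 gene symbol for 23525 rows, several for 1816, and does not list 16004. Only rows with 1 symbol were used, for 22184 genes, 1082 of which have more than 1 row. The row with the highest mean over the 4 arrays stood for its gene. The expression floor was the median of all rows with a gene symbol over the arrays, 4.57. The files used here hold no detection calls, so this floor is only a convention. A gene counted as different where its log2 difference between 2 arrays was at least 1 in size (2-fold) and its brighter array was at or above the floor. Where the dimmer array lay under the floor, a fold of the brighter array over the floor was also computed.

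With 1 array per group no test, error or p-value was possible, and the counts describe 4 ovaries. As a guide to measurement noise, among the 335 genes with several expressed rows, the SD of a log2 difference between rows of a gene was 0.265 for genotype, 0.284 for eCG and 0.31 for E2. Over the genes whose brighter array reached the floor, the central 95% of differences ran from -0.76 to 0.83 for genotype. It ran from -0.71 to 0.78 for eCG and from -0.92 to 0.84 for E2. The row spread leaves out differences between animals. The comparisons were the untreated knockout minus the untreated wild type (genotype), the eCG-treated minus the untreated wild type (eCG), the estradiol-treated minus the untreated knockout (E2), and the estradiol-treated knockout minus the untreated wild type (the remaining difference).

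Before the data were examined, 26 gene lists were fixed: steroidogenesis, cholesterol synthesis and uptake, immediate early genes, cAMP and FSH targets, ovulatory genes, estrogen-responsive genes, cell cycle, extracellular matrix, glucocorticoid-responsive genes, circadian clock, heat shock, housekeeping, and markers of granulosa, theca and interstitial, Sertoli and Leydig, oocyte, luteal, macrophage, lymphocyte, neutrophil, mast, endothelial, smooth muscle and pericyte, surface epithelium and oviduct, adipocyte and erythrocyte cells. Some genes stand in several lists. Of 445 distinct entries, 402 had a row with 1 symbol. For each list and comparison the median log2 difference over members whose mean reached the floor was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these arrays and is no p-value over animals. Of 100 such medians, 49 lay outside the percentiles 2.5 to 97.5, against 5 by chance for independent lists.

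The genes named are, per comparison, the 12 largest increases and the 12 largest decreases among those counted, leaving out predicted, clone-derived, olfactory and vomeronasal receptor, microRNA, small nucleolar or nuclear RNA, immunoglobulin, T cell receptor and histone names; up to 4 members with the largest difference of each list among those counted; and always Cyp19a1, Esr1, Esr2, Gper1, Fshr, Lhcgr, Pgr and Ar, of which Cyp19a1, Lhcgr and Ar have no row with 1 symbol. This rule was also fixed beforehand.

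Pairs of comparisons were correlated across the 11381 genes whose mean reached the floor. For pairs with a shared array, the correlation and covariance expected without any effect were simulated in 100 sets with a noise SD of 0.17 per array. This SD, the same for every array, was estimated from the spread of the remaining difference, and so is not independent of real differences. Overlaps of counted genes were set against the product of the list sizes over the genes above the floor in both comparisons. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The scripts were tested on simulated arrays of 22184 genes with 200 changed genes and a noise SD of 0.2. Log2 changes of 1.5 were counted in 94% of cases for genotype, 96% for eCG and 98% for E2, and changes of 2 and 3 in 100%. The changed genes were drawn only from genes with a mean well above the floor. These rates therefore do not cover genes near or under it, and the simulated noise held no differences between animals. Alternatives were other fold limits and floors, subtraction of array medians, quantile normalization, removal of a loess trend (span 0.3), the mean of a gene's rows, all rows, all members of a list, 10 bins, rank correlation and all genes. Further alternatives, chosen after seeing the data, set each treated array against all other arrays and used the other pair of arrays of both genotypes.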

Results

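Gene expression was measured in 4 whole mouse ovaries, each on 1 array, from females at 4 weeks of age. An untreated wild-type mouse gave 1 ovary. A further ovary came from a wild-type mouse 4 h after 5 IU of equine chorionic gonadotropin (eCG), a placental hormone. The other pair came from estrogen-deficient ArKO mice, in which Cyp19a1, the gene of the estrogen-forming enzyme aromatase, is disrupted. One of these was untreated and the other was collected 4 h after 18 mg/kg of estradiol (E2) in sesame oil. With 1 array per group no difference below has a replicate check, an error or a p-value. All differences are between single ovaries. The array number limits the precision, and no control ovary was injected with vehicle.

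The 4 value distributions were nearly alike, with array medians between 4.02 and 4.06 on the log2 scale. Across the 11381 genes whose mean reached the expression floor of 4.57, the untreated wild-type and the estradiol-treated knockout ovary were the closest pair, with a Pearson correlation across genes of 0.977. The eCG-treated wild type and the untreated knockout were the farthest, at 0.953. The targeted gene Cyp19a1 had no array row that names it alone, so the knockout could not be checked at its own transcript and Cyp19a1 is not analysed here. The same holds for the LH receptor gene Lhcgr and the androgen receptor gene Ar. In the 13 measured housekeeping genes the median difference stayed between -0.09 and 0.05 in the 4 comparisons; in that of the treated knockout with the untreated wild type it was -0.03 and the mean 0.03. Of the neutrophil list none of 10 measured members had a mean at the floor, and of the lymphocyte list 1 of 13. Of the 10 erythrocyte genes 3 had a row, none of them a globin gene, and 2 of these reached the floor, with medians between -0.09 and 0.06.

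The comparison of the untreated ovaries asked which transcripts differ when estrogen synthesis is absent. The knockout ovary had higher levels of genes that mark Sertoli and Leydig cells of the testis and lower levels of smooth muscle and endothelial markers. Eppin, a protease inhibitor of the male tract, stood at 9.44 in the knockout and 6.34 in the wild type, which is 8.56-fold. Cldn11, the tight junction protein that Sertoli cells make, stood at 8.45 and 6.20. In the other direction the secreted glycoprotein Stc1 was 14.0-fold lower in the knockout (5.20 against 9.01) and the glutamine transporter Slc38a3 was 12.4-fold lower (5.01 against 8.65). In all, 352 of the 11774 genes whose brighter array reached the floor differed by 2-fold or more, 183 of them higher and 169 lower in the knockout.

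Among the largest increases were the bone matrix protein Ibsp (7.03 against 2.69), the mast cell protease Cpa3 (7.71 against 3.48), the mRNA export family member Nxf3 (9.66 against 5.62) and the carbonic anhydrase Car12 (8.91 against 5.11). The Wnt antagonist Sfrp4, the ferritin receptor Scara5, the protease inhibitor Wfdc6b, the collagen Col8a1, Adam23, the opioid precursor Penk and Bves followed, with log2 differences between 2.44 and 3.02. The wild-type values of Ibsp, Cpa3, Sfrp4, Wfdc6b and Col8a1 lay under the floor, so the size of these differences is uncertain. Counted from the floor, Ibsp was 5.5-fold and Cpa3 8.8-fold higher in the knockout. The largest decreases after Stc1 and Slc38a3 were in the serine protease Prss23 (-3.52), Mboat1 (-3.34), the angiotensin-cleaving aminopeptidase Enpep (-3.11), the growth factor Bmp3 (-2.90), the small proteoglycan Lum (-2.68) and the vascular growth factor Angpt2 (-2.64). Thbs4, Otor, Aspn and Sncaip followed, between -2.36 and -2.21. The knockout values of Mboat1, Enpep, Angpt2 and Otor lay under the floor, so their sizes and ranks are uncertain. Counted from the floor, their wild-type values were 5.8-, 8.0-, 5.0- and 2.4-fold higher. Both rows of Prss23 were lower, by -3.52 and -3.22.

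Of the 19 measured genes of the Sertoli and Leydig cell list, 6 were higher by 2-fold or more and none was lower. Cldn11, the prostaglandin D synthase Ptgds (1.78), Aard (1.76) and the defensin Defb19 (1.48) led this group. The median over its 15 expressed members was 0.80, above all 10000 random lists of the same size and expression (percentile 100). The Sertoli cell transcription factors Sox9 and Dmrt1 did not differ by 2-fold, with log2 differences of 0.21 and 0.22. Dmrt1 lay under the floor on all arrays. Sox9 lay close to it, at 4.72 in the knockout and 4.51 in the wild type, so neither row says much about a difference. Both were named after their values were seen. Steroidogenic genes went both ways. Star, the cholesterol carrier of the mitochondrion, was higher (8.41 against 7.15), while Akr1c14 and the steroidogenic factor Nr5a1 were lower, with differences of -1.54 and -1.38. The list median was 0.27 (percentile 99.95). Hsd3b6 was counted as higher at 4.57 against 2.28, exactly at the floor. Cholesterol synthesis genes were higher by a median of 0.45 (percentile 100), none of the 17 by 2-fold. The theca and interstitial list had a median of 0.37 (percentile 99.96), with Hsd3b6, Star and the retinaldehyde dehydrogenase Aldh1a1 at 2-fold. Of the 9 members in this median, 5 lay above 0 and 4 below, and Hsd3b6, with a mean under the floor, is not among them.

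Structural and vascular markers were lower in the untreated knockout. The smooth muscle and pericyte list had a median of -0.97 (percentile 0), with Cnn1 (-1.71), Tagln (-1.25), Actg2 (-1.14) and Acta2 (-1.05) at 2-fold or more lower. The endothelial list had a median of -0.49 (percentile 0), and all 10 expressed members lay below 0, Emcn at -1.10. In the extracellular matrix list 4 genes were lower by 2-fold, Lum, Thbs1 (-1.23), Lox (-1.05) and Adamts5 (-1.05), yet the list median was 0.00 (percentile 49.3), with a mean of -0.10. The oocyte list had a median of -0.22 (percentile 0.06), and the growth factor receptor Kit (-1.10) was its only member at 2-fold. The surface epithelium and oviduct list had a median of -0.28 (percentile 0.39).

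Markers that can follow stress or other cells also differed between the untreated ovaries. Immediate early genes had a median of 0.23 (percentile 99.96) and a mean of 0.10. They were split, with 14 expressed members above 0 and 11 below, and only Btg2 (1.03) reached 2-fold. The glucocorticoid-responsive list was higher in the knockout by a median of 0.68 (percentile 100), with Zbtb16 (2.27), Lcn2 (1.75) and Ddit4 (1.33) at 2-fold. The macrophage list was higher by 0.45 (percentile 100), with no member at 2-fold. Of the mast cell list only Cpa3 and Hdc reached the floor, with a median of 2.68 (percentile 100). The adipocyte list was higher by 0.33 (percentile 99.4), with the fatty acid desaturase Scd1 at 1.61. Clock genes had a median of 0.11 (percentile 90.7), with Npas2 at 1.39, and heat shock genes had a median of 0.05 (percentile 70.3). Granulosa cell genes had a median of 0.04 (percentile 79.0), with Kitl at 1.34 and Grem1 at -1.15. The ovulatory list had a median of 0.26 (percentile 99.9), with Zbtb16, Ptgs2, Rgcc and Vcan at 2-fold or more higher. The estrogen-responsive list had a median of -0.09 (percentile 2.74). Within it Susd3 was higher (1.59) and Npr2, the receptor of C-type natriuretic peptide, was lower (-1.27). Neither estrogen receptor gene differed by 2-fold, with Esr1 at 0.52 and Esr2 at -0.30. The FSH receptor gene Fshr was at 0.64 and Gper1, under the floor on all arrays, at 0.25.

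The comparison of the wild-type ovaries asked what the gonadotropin does within 4 h. The eCG-treated ovary had much higher levels of genes of the ovulatory and steroidogenic programmes. Ptgs2, the inducible cyclooxygenase, stood at 9.58 after eCG and 4.00 in the untreated ovary, and the cumulus matrix protein Tnfaip6 at 8.42 and 3.14. Star stood at 11.34 and 7.15, which is 18.2-fold. The estrogen sulfotransferase Sult1e1 stood at 8.54 and 1.93. Of 11751 genes, 172 were higher and 92 lower by 2-fold or more, 264 in all. Over all array rows, named or not, 395 were higher and 369 lower.

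Also among the largest increases were Ch25h (5.04), the neuropeptide precursor Nts (4.91), the EGF-like factors Ereg (4.60) and Btc (3.68), Sfrp4 (4.50), the nuclear receptor Nr4a3 (3.79), the progesterone receptor Pgr (3.76) and the tissue factor F3 (3.28). The untreated values of Sult1e1, Ptgs2, Tnfaip6, Ch25h, Nts, Sfrp4, Nr4a3, Pgr and Btc lay under the floor. Counted from the floor, Ptgs2 was 32.3-fold, Sult1e1 15.7-fold, Tnfaip6 14.4-fold and Pgr 3.8-fold higher. Ch25h and Ereg have 2 rows each. The dimmer rows showed 0.39 and 1.47. The largest decreases were in Stc1 (6.37 against 9.01), the pseudogene Mug-ps1 (-2.49), which has close paralogs that may share its probes, Phex (-2.39), Capn6 (-2.27), Epha5 (-2.25), the versican-cleaving protease Adamts5 (-2.10), Lrat (-1.97) and Abcd2 (-1.71). Ntng1, Krt20, Tmem182 and Lpar4 followed, between -1.70 and -1.43. After eCG the values of Mug-ps1, Epha5, Lrat, Ntng1 and Krt20 lay under the floor, so their sizes and ranks are uncertain. The untreated value of Epha5 was 1.2-fold over the floor. The genotype and eCG comparisons share the untreated wild-type array, which alone gives a positive relation. Of the 2-fold genes, 34 were lower in both, against 1.3 for independent lists, and 21 higher in both, against 1.7. In opposite directions there were 1 and 5, against 1.1 and 2.0. Stc1 was highest in that shared array, so its decreases in both comparisons are not separate results.

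Of 24 measured ovulatory genes, 15 were higher by 2-fold or more and none lower. The median over 17 expressed members was 1.09 (percentile 100). In the cAMP and FSH target list 12 of 30 measured genes were higher and none lower, with a median of 0.61 (percentile 100). Immediate early genes, which follow many stimuli, were higher in 11 of 28 cases, with a median of 0.84 (percentile 100). Nr4a1 (3.27), Ier3 (2.37) and Egr1 (1.85) led this list after Nr4a3. In the steroidogenesis list 7 of 15 measured genes were higher, among them Star, Sult1e1, the electron carrier Fdx1 (2.75) and the lipoprotein receptor Scarb1 (1.65). That list's median was 0.30 (percentile 99.95), and it was 0.94 with members under the floor included. The cytochromes Cyp17a1 (11.61 against 10.18) and Cyp11a1 (11.22 against 9.82) were higher, but a second row of Cyp11a1 showed -0.01, and the mean of both rows was 0.69. Cholesterol synthesis genes had a median of 0.68 (percentile 100), with Cyp51 (1.97), Dhcr7 (1.48), Sc5d (1.16) and Sqle (1.06) at 2-fold.

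The luteal list had a median of 0.98 (percentile 99.99), with Sfrp4, Scarb1 and Parm1 (1.22) at 2-fold. The estrogen-responsive list had a median of 0.35 (percentile 100), led by Pgr, Egr1, Vegfa (1.31) and Rasd1 (1.24); 3 of these 4, Pgr, Egr1 and Vegfa, stand in other lists that were higher, and Txnip (-1.05) was its only lower member at 2-fold. Among granulosa cell genes only Nr0b1 (-1.29) and the estrogen receptor Esr2 (8.94 against 9.98) reached 2-fold, both lower, and the list median was -0.02 while its mean was 0.03. Esr1, Fshr and Gper1 were at -0.35, -0.22 and 0.10. The matrix list held 3 higher genes, Adamts4 (1.73), Adamts1 (1.69) and the inhibitor Timp1 (1.32), and its median of -0.11 (percentile 7.0) differed in sign from its mean of 0.01. The theca and interstitial list had a median of 0.02 (percentile 65.0), with Star, Cyp17a1 and Cyp11a1 at 2-fold.

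Genes that can follow injection or handling were higher too in this ovary. The glucocorticoid-responsive list had a median of 0.57 (percentile 100), with Errfi1 (1.69), Sgk1 (1.15), Zbtb16 (1.09) and Ddit4 (1.07) at 2-fold. Sgk1 also stands in the cAMP and FSH target list and Zbtb16 in the ovulatory list. The same list had a median of 0.68 in the genotype comparison, between untreated ovaries, and of -0.42 in the E2 comparison. All 11 heat shock genes lay above 0, with a median of 0.31 (percentile 99.96), none at 2-fold. Their median in the E2 comparison was -0.47. The clock list had a median of 0.18 (percentile 98.2), with Bhlhe40 (1.75) and Cry2 (1.07) at 2-fold. The histamine-forming enzyme Hdc, in the mast cell list, was higher by 1.40, while Cpa3 was not (0.05). The adipocyte list had a median of 0.52 (percentile 99.96), with Retn at 1.06. Smooth muscle, endothelial, macrophage, oocyte, epithelial and cell cycle lists had medians between -0.06 and 0.08, with percentiles between 31.2 and 78.1.

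**Figure D1:**
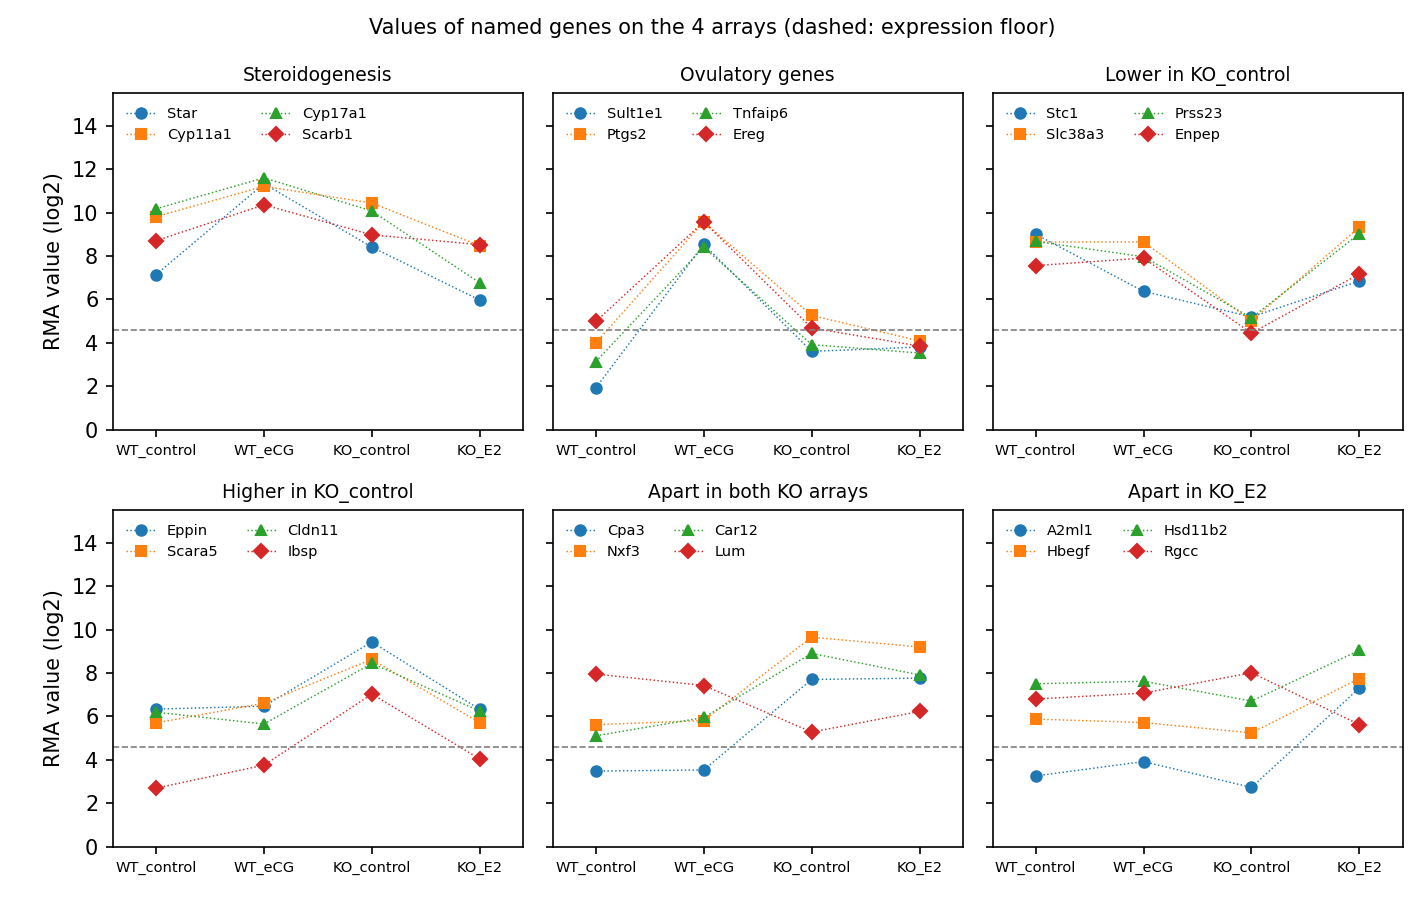
RMA values (y axis, log2) of 24 genes on the 4 arrays (x axis), 1 point per gene and array; dotted lines only join the values of a gene, and the dashed line is the expression floor of 4.57. Star stood at 11.34 in the eCG-treated wild type and at 5.97 in the estradiol-treated knockout, and Cpa3 at 7.71 and 7.77 in both knockout ovaries against 3.48 and 3.53 in both wild types.

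The comparison of the knockout ovaries asked what estradiol does within 4 h in an ovary that lacks it. Leading genes of the steroidogenesis list were lower after estradiol. Cyp17a1, the enzyme that forms androgens, stood at 6.77 after estradiol and 10.08 without, which is 9.95-fold lower. Star stood at 5.97 and 8.41, and Cyp11a1 at 8.48 and 10.45, where a second row differed by -0.93. Slc38a3 (9.33 against 5.01), Prss23 (9.03 against 5.15) and Angpt2 (7.61 against 4.24), all low in the untreated knockout, were higher. Of 11796 genes, 213 were higher and 225 lower by 2-fold or more, 438 in all.

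Slc38a3 was higher by 4.32 and Prss23 by 3.88, with both arrays above the floor. The protease inhibitor A2ml1 stood at 7.31 against 2.73, 6.7-fold when counted from the floor. The kallikrein Klk1, with close paralogs that may share its probes, was higher by 3.45, Rgs13 by 3.21, Mboat1 by 3.04, Klhl31 by 2.84, Enpep by 2.73, Mug-ps1 and Bmp3 by 2.68 and Tbc1d30 by 2.66. Without estradiol A2ml1, Klk1, Angpt2, Mboat1, Enpep and Tbc1d30 lay under the floor, so the sizes of these differences and their order are uncertain. The largest decreases after Cyp17a1 were in Eppin (-3.11), Ibsp (-2.99), the dopamine receptor Drd4 (-2.96), Scara5 (-2.92), Wfdc6b (-2.75) and Cnih2 (-2.49). Star (-2.44), Rgcc (-2.39), Tmem184a, the amino acid transporter Slc7a8 and Enc1 (-2.21) followed. After estradiol Ibsp, Drd4 and Wfdc6b lay under the floor, and the same holds for the sizes of these.

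In the steroidogenesis list Akr1c14 (1.73) and 1 more of 15 genes were higher and Cyp17a1, Star and Cyp11a1 lower, with a median of -0.45 (percentile 0). Cholesterol synthesis genes had a median of -0.48 (percentile 0), with Msmo1 at -1.09. In the theca and interstitial list 4 of 11 genes were lower, Aldh1a1 (-1.22) among them, and 1 was higher, Hhip (1.17). The median was -0.44 (percentile 0.02). In the Sertoli and Leydig cell list 5 of 19 genes were lower, among them Cldn11 (-2.20), Gdnf (-1.65), Defb19 (-1.48) and Dhh (-1.37), and 1 was higher. That median was -0.63 (percentile 0). Granulosa genes Kitl (-1.23) and the AMH receptor Amhr2 (-1.23) were lower, with a list median of -0.16 (percentile 3.48).

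The estrogen-responsive list had a median of 0.15 (percentile 99.9). Npr2 (1.81) and the corepressor Nrip1 (1.35) were higher, and Susd3 (-1.98) and the cyclin Ccnd2 (-1.35) lower. Pgr stayed under the floor on both arrays, at 3.31 and 2.61. Esr1 was at -0.76, Esr2 at 0.03, Fshr at -0.16 and Gper1 at -0.77. Ovulatory genes had a median of -0.45 (percentile 0.03), with 7 of 24 lower, among them Rgcc, Zbtb16 (-1.95), Rhox8 (-1.34) and Vcan (-1.27), and 1 higher. With members under the floor included, the median was -0.22. The cAMP and FSH target list held 3 higher genes, Irs2 (1.47) among them, and 5 lower, Per1 (-1.51) among them, with a median of -0.07 (percentile 27.5). Immediate early genes had a median of 0.04 (percentile 89.2), with Btg2 lower (-1.55), and their mean of -0.09 had the opposite sign. All but 3 of the 30 cell cycle genes lay below 0, with a median of -0.24 (percentile 0.07) and none at 2-fold.

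Smooth muscle and endothelial lists were higher after estradiol, with medians of 0.57 (percentile 100) and 0.43 (percentile 99.98) and no member at 2-fold. The matrix list had a median of -0.02 (percentile 63.7), or 0.02 with a loess trend removed. Lama1 (-1.93), Adamts1 (-1.12) and Eln (-1.04, under the floor after estradiol) were lower, and Adamts5 (1.35) and Thbs1 (1.08) higher. Glucocorticoid-responsive genes had a median of -0.42 (percentile 0.02), with Ddit4 (-2.21), Zbtb16, Per1 and Sgk1 (-1.19) lower. Heat shock genes had a median of -0.47 (percentile 0.03), with Hspa1b at -1.95; Hspa1b and Hspa1a are near-identical, so their rows may share signal. Clock genes had a median of -0.22 (percentile 5.76). Scd1 (-1.86) and the nuclear receptor Pparg (1.24) of the adipocyte list went in opposite directions, and that list's median was 0.18 (percentile 95.3). The epithelial list's median of -0.16 (percentile 20.7) differed in sign from its mean of 0.08 and from the median of 0.20 with members under the floor; the stem cell marker Lgr5 was higher by 1.01, but by 0.69 as the mean of its rows. The macrophage median was 0.05 (percentile 87.4) and its mean -0.05. The oocyte and luteal medians were -0.15 (percentile 11.9) and -0.16 (percentile 22.1).

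**Figure D2:**
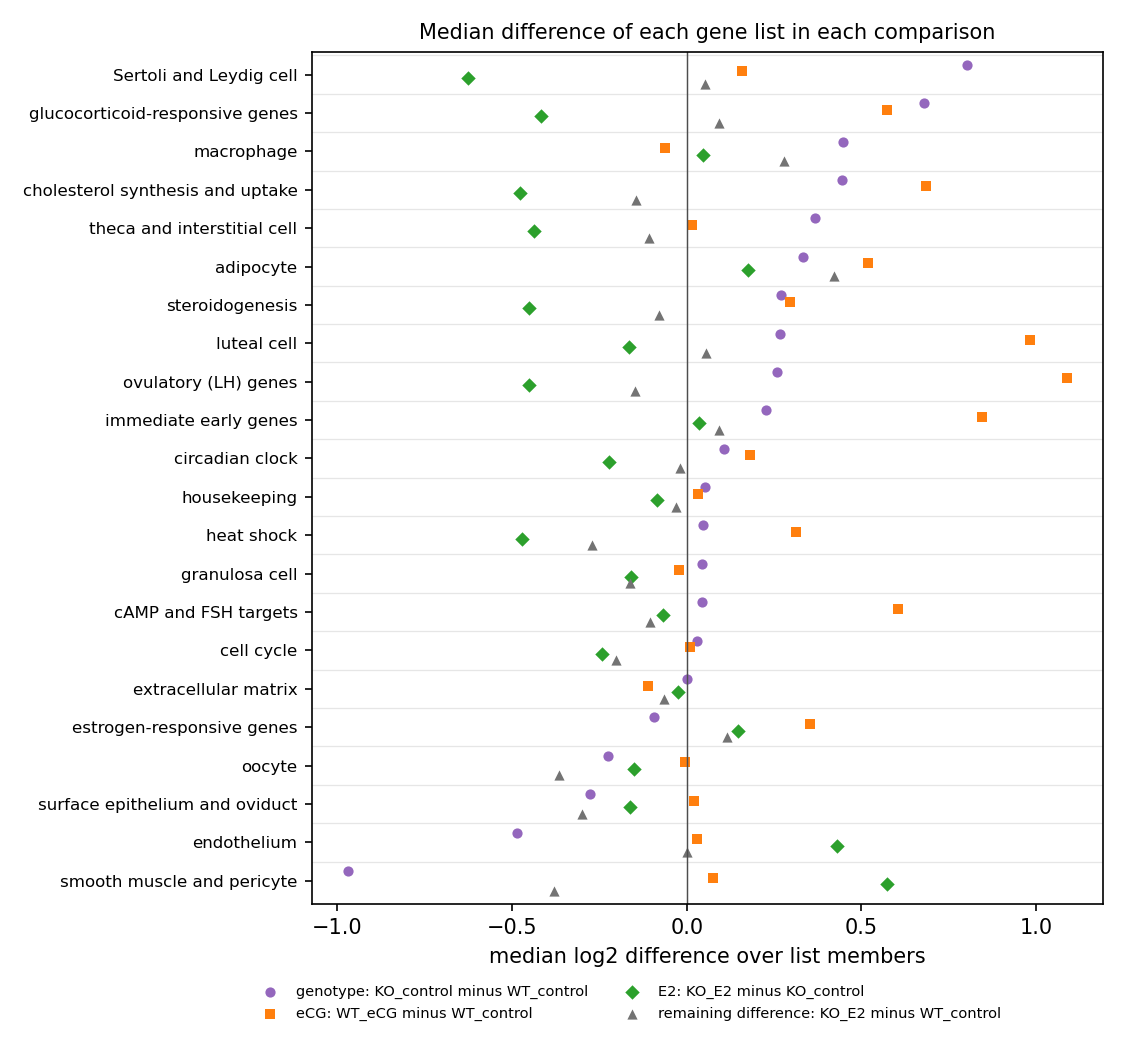
Median log2 difference (x axis) of the gene lists with at least 5 expressed members (y axis), 1 marker per comparison. The smooth muscle list lay at -0.97 in the genotype comparison and 0.57 in the E2 comparison, and the ovulatory list at 1.09 in the eCG comparison.

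The estradiol-treated knockout was then set against the untreated wild type, to see which differences were left. Of 11763 genes, 145 stood at 2-fold or more, 72 higher and 73 lower. Cpa3 (7.77 against 3.48), Nxf3 (9.21 against 5.62), Car12 (7.92 against 5.11) and Sfrp4 (5.24 against 3.07) were among those that were also higher in the untreated knockout. A2ml1 (4.06), Lcn2 (2.08), Dhrs9 (2.04), the EGF-like factor Hbegf (1.87), the copper protein Cp (1.84), the urokinase Plau (1.78), Klk1 (1.70) and Plet1 (1.63) completed the largest increases. Cyp17a1 showed the largest decrease (6.77 against 10.18), followed by Bpifb4 (-2.33), Stc1 (-2.16), Slc9a3 (-2.04), Lrat (-2.03), Slc6a15 (-1.73), Lum (-1.72), Cntn4 (-1.69), Hspa1b (-1.65) and Gulo (-1.45). Krt20 and Tmem229b-ps were both at -1.44. Stc1, Lrat and Krt20 were also low in the eCG-treated wild type, at 6.37, 4.25 and 3.99. The eCG comparison shares the untreated wild-type array, so these decreases are not separate results and are not particular to the knockout. The wild-type values of Cpa3, A2ml1, Sfrp4, Lcn2 and Dhrs9 and the knockout values of Bpifb4, Slc9a3, Lrat and Krt20 lay under the floor, so the sizes of these differences are uncertain. Star was lower by -1.18 and Cyp11a1 by -1.34, but the mean of the rows of Cyp11a1 was -0.84.

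All 20 expressed oocyte genes lay below the wild type in the treated knockout, with a median of -0.37 (percentile 0) and none at 2-fold. Cell cycle genes had a median of -0.20 (percentile 0.03), heat shock genes -0.27 (percentile 0.52), smooth muscle genes -0.38 (percentile 0.11), granulosa cell genes -0.16 (percentile 0.68) and epithelial genes -0.30 (percentile 1.13). Slc18a2 (-1.14) was the only granulosa gene at 2-fold. Macrophage genes had a median of 0.28 (percentile 99.97), with the mannose receptor Mrc1 at 1.19, and adipocyte genes 0.42 (percentile 99.9), with Car3 at 1.02. The endothelial median was 0.00 (percentile 76.4), with a mean of -0.07, and the Sertoli and Leydig median 0.05 (percentile 89.1), with Mro at 1.15. Rgcc (-1.18) and Lama1 (-1.17) were also lower; Ereg was lower by -1.14, but by -0.61 as the mean of its rows. Esr1, Esr2, Gper1, Fshr and Pgr lay within 2-fold, at -0.24, -0.27, -0.52, 0.48 and 0.57.

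Setting the genotype and E2 differences side by side asked whether transcripts that differed in the knockout moved back after estradiol. Of the 183 genes higher in the untreated knockout, 178 were lower after estradiol than before and 159 lay within 2-fold of the wild type. Of the 169 lower genes, 160 were higher after estradiol and 141 lay within 2-fold. Among genes above the floor in both comparisons, 108 were higher in the knockout and lower after estradiol and 95 the reverse, against 3.6 and 2.5 for independent lists, and none moved the same way at 2-fold in both. Both comparisons use the untreated knockout array with opposite signs, which alone gives a negative relation. The correlation across genes was -0.713 (Spearman -0.625) against -0.501 simulated without any effect. The covariance was -0.120 against -0.0291, a difference of -0.0908. The simulation gave every array the same noise, estimated from a pair that leaves out the untreated knockout. An untreated knockout array with more noise, or that stood apart for another reason, would also give a more negative relation. The excess alone therefore does not show a return after estradiol. Part of these overlaps may come from the shared array. With no shared array, the genotype difference of the untreated arrays and that of the treated arrays correlated at -0.114.

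**Figure D3:**
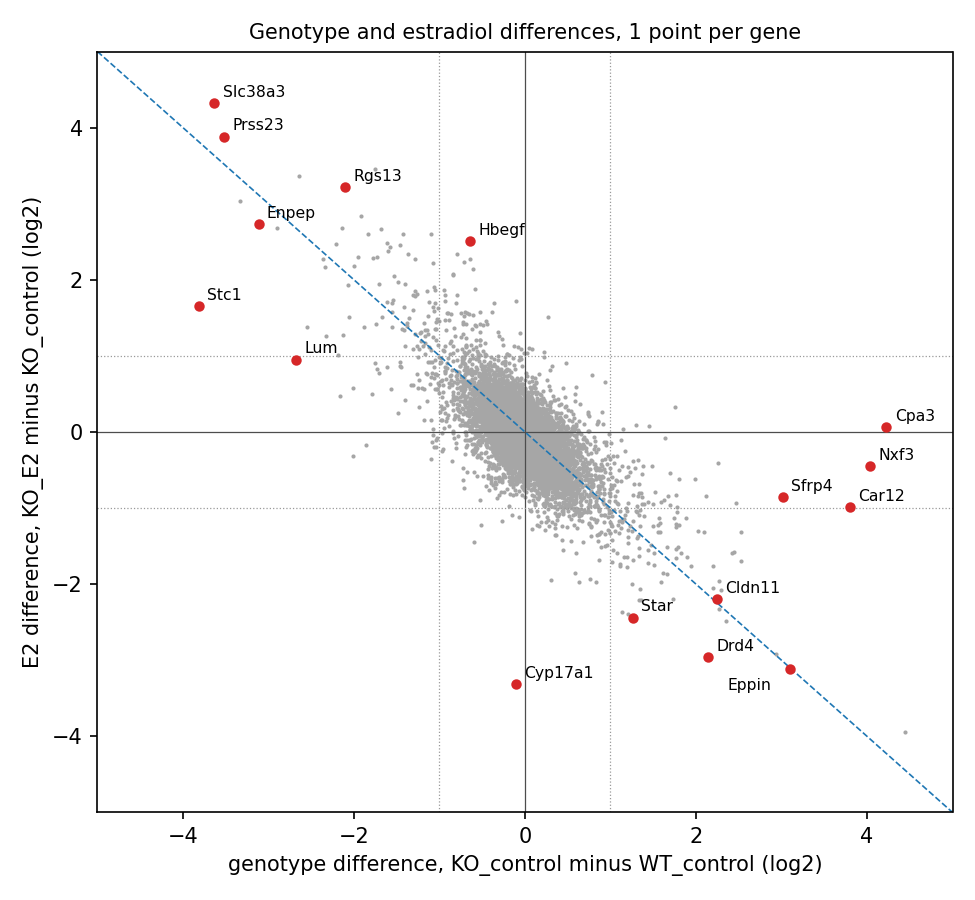
Difference between the untreated ovaries (x axis, knockout minus wild type, log2) against the E2 difference in the knockout (y axis, log2), 1 point per gene for the 11381 expressed genes; dotted lines mark 2-fold and the dashed line marks a full return to the wild-type level. Eppin and Cldn11 lie near the dashed line, Cpa3 and Nxf3 near 0 on the y axis, and Cyp17a1 near 0 on the x axis; the points share the untreated knockout array on both axes, with opposite signs.

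The eCG and E2 differences, which share no array but come from different genotypes, ran in part in opposite directions. Star was higher after eCG (4.19) and lower after estradiol (-2.44), as was Cyp17a1 (1.43 and -3.31). Cyp11a1 was at 1.40 and -1.97 in its brighter row but at -0.01 and -0.93 in its other row. Of the 2-fold genes, 26 were higher after eCG and lower after estradiol, against 2.5 for independent lists, and 15 the reverse, against 1.4. A further 8 were higher after both, against 2.4, and 0 were lower after both, against 1.5. Across genes, which are not independent replicates, the Pearson correlation was -0.151, Spearman's rho -0.125 and the covariance -0.025.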

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

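Rows without a gene name also held differences and are outside the comparisons above. The annotation does not list 16004 rows. Of these, 150 were higher by 2-fold or more in the untreated knockout than in the untreated wild type, 211 were higher after eCG than in the untreated wild type, and 206 were higher after estradiol than in the untreated knockout. Lower were 196, 271 and 214. They were set apart because they differ from the control array in data that carry no name. The rows at or above the floor numbered 4947, 5010 and 4950. Of them 7.0%, 9.6% and 8.5% differed by 2-fold or more, against 2.99%, 2.25% and 3.71% of the named genes. In the remaining difference, between the closest pair of arrays, 169 unnamed rows were higher and 244 lower. These were 8.2% of 5012 rows, against 1.23% of the named genes. The share was of similar size in every comparison, so these counts are not read as responses. After eCG more unnamed rows were lower than higher, while more named genes were higher than lower.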

How the results depend on the processing

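Each count was recomputed under the other settings, and no named difference at 2-fold changed sign. Array medians, quantile normalization, loess and the mean of a gene's rows kept the counts between 333 and 353 (genotype), 253 and 266 (eCG), 417 and 438 (E2) and 138 and 153 (remaining difference). The split of higher and lower genes was near even for E2 (213 and 225) and the remaining difference (72 and 73) and turned with scaling: with loess it was 238 and 197, and 87 and 64, and with array medians 211 and 226, and 68 and 79. Array medians, loess and quantile normalization each moved the median of all genes by under 0.1. The fold limit and floor moved counts by their construction. At 1.5-fold there were 1095, 1123, 1501 and 801 genes for genotype, eCG, E2 and the remaining difference, and at 3-fold 109, 67, 129 and 23. The share of higher genes after eCG was 50.8% at 1.5-fold, 65.2% at 2-fold and 80.6% at 3-fold, and 51.7% at 2-fold over all rows, named or not. A floor at the upper quartile left 209, 168 and 85 genes for genotype, eCG and the remaining difference. No floor gave 252 for the remaining difference. All rows, named or not, gave 729, 764, 885 and 567. Chosen after seeing the data, a 2-fold distance from each of the other 3 arrays left 97 genes for eCG and 34 for E2, fewer because more must hold. The other pair of arrays of both genotypes, also chosen afterwards, gave 371 genes, with 39.1% higher in the knockout against 52% in the main comparison; it mixes genotype with both treatments. The genotype and E2 correlation of -0.713 became -0.114 for the pair with no shared array, which asks about different differences; the cause was not tested. Of 194 named values at 2-fold, 4 fell under 2-fold, all as the mean of a gene's rows. Of the 100 list medians, 24 moved with all measured members, 2 with loess and 2 with 10 bins. In 9 of them the sign differed in at least 1 setting; 8 were within 0.1 of 0, and the epithelial E2 median of -0.16 was 0.20 with all members. Values under the floor limit the sizes and the counts. With both arrays at or above the floor, 240, 198, 334 and 100 genes were left for genotype, eCG, E2 and the remaining difference. Leaving out an array was not possible with 1 per group. No paired analysis was possible because each group has 1 array.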

Other observations

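The tests of injection or hour, of gonadotropin-dependent transcripts and of mast cells were chosen only after the results were seen, as were the genes and groups of the next 3 paragraphs.

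A set of 34 genes stood at 2-fold or more from all 3 other arrays in the estradiol-treated knockout, 20 higher and 14 lower. Among the higher ones were Hbegf (7.75 against at most 5.88 elsewhere), Hsd11b2, the enzyme that inactivates glucocorticoids (9.05 against at most 7.62), the hypoxia factor Epas1 (10.24 against at most 9.19), the growth factor Tgfb2 (7.28 against at most 6.27), the Wnt antagonist Frzb (6.83 against at most 5.71) and the retinol dehydrogenase Dhrs9 (5.28 against at most 3.88). Among the lower ones were Star and Cyp17a1 together with the actin bundler Fscn1 (7.10 against at least 8.24) and Ppp1r16b (6.18 against at least 7.32). Cyp11a1 is counted too, by its brighter row, but as the mean of its rows it lay -0.84 from the untreated wild type, under 2-fold. By the same rule 97 genes stood apart in the eCG-treated wild type, 84 of them higher, and 14 in the untreated wild type.

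Rian, a long noncoding RNA of the imprinted Dlk1 and Meg3 region, was lower in the untreated knockout than in the untreated wild type (5.21 against 6.95) and stood at 6.63 after estradiol. The gene table of assembly GRCm38.p6 places 5 measured small nucleolar RNA genes inside Rian. Of these, 3 were lower by 2-fold or more in the untreated knockout, AF357355 by -2.55, AF357425 by -2.07 and DQ267102 by -2.13, and the same 3 were higher after estradiol, by 1.37, 1.94 and 1.27. On the arrays of these comparisons AF357426 and DQ267101 lay under the floor, so they are not counted. The neighbour Meg3 lay under the floor on all arrays. The rows lie inside 1 host transcript, so they are not independent. Over the 59 expressed genes named Snor the median was -0.56 for genotype, with 56 below 0, -0.39 for eCG and 0.07 for E2, so these RNAs were highest in the untreated wild type. Expressed microRNA rows, 84 in number, had medians between -0.03 and 0.04.

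The predicted gene Gm5294 had the largest genotype difference of the genes counted, 9.24 in the untreated knockout against 4.80 in the untreated wild type, and stood at 5.31 after estradiol and 6.08 after eCG. Npr2 was lower in the untreated knockout (-1.27) and higher after estradiol (1.81); its ligand gene Nppc was higher after estradiol (1.02), with a genotype difference of -0.62 that did not reach 2-fold. The ovarian factor Foxl2 was at 0.65 for genotype and -0.68 for E2, so it was not lower in the ovary with higher Sertoli markers.

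Most genes that differed in the untreated knockout lay within 2-fold of the wild type 4 h after estradiol. Noise of the shared array that is independent between rows is argued against, as the sole source, by genes with several expressed rows. Between the 2 brightest rows of a gene, the genotype difference of 1 row and the E2 difference of the other were correlated. The correlation was -0.53 over 335 genes (bootstrap interval -0.704 to -0.268), where independent noise gives 0. Without Prss23 and Me3, the largest differences, it was -0.318 (-0.408 to -0.222). Both rows were read from the same RNA on the same array, so noise that moves them together was not tested. Whether the rows share probes was not checked, and the bootstrap resampled genes, not arrays. An untreated knockout ovary that stood apart for a reason other than estrogen deficiency cannot be told apart from a return after estradiol, since each group has 1 ovary; the untreated knockout stood 2-fold from all other arrays in 132 genes, more than any other array. Of the E2 genes, 7.8% stood 2-fold from all others in the treated knockout, Cyp17a1 and A2ml1 among them. For these genes, an untreated knockout that stood apart is not enough by itself. Whether they follow estradiol or the treated animal cannot be told with 1 ovary per group. By the same rule 14 genes stood apart in the untreated wild type.

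The eCG and E2 differences ran in part in opposite directions. The injection or the hour of collection, shared by both treated ovaries, would push genes the same way; 8 genes were higher after both, against 2.4 for independent lists, and 0 lower, against 1.5. This leaves open how much of each difference comes from them, with no vehicle-injected ovary. A candidate explanation is that transcripts that depend on gonadotropins were lower after estradiol. The cAMP and FSH target list, fixed beforehand, had a median E2 difference of -0.07 (percentile 27.5), with 15 of 27 members below 0, and the ovulatory list -0.45 (percentile 0.03), so these lists do not decide it. The 150 expressed genes higher after eCG had a median of -0.26, which restates the pattern. For the genes as a set, the explanation cannot be told apart from a return of the untreated knockout towards the wild type. Cyp17a1 and Star stood lower in the treated knockout than in the untreated wild type (6.77 against 10.18 and 5.97 against 7.15). For them a return alone is not enough, but each value comes from 1 ovary. The different genotypes of both comparisons cannot be told apart from the explanation for any of these genes.

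In 12 genes both knockout arrays stood 2-fold above both wild-type arrays, with gaps of 4.18 for Cpa3, 3.39 for Nxf3, 1.96 for Car12, 1.84 for Cp and 1.45 for the complement gene C7, and 3 genes stood below, Lum, Grik3 and DQ267101. DNA of another strain around the targeted locus, carried along in breeding, is argued against as the source of most: of the 13 that are protein coding in the gene table, 1, Car12, lies within 300 genes of Cyp19a1, against 0.37 by share, and for Car12 it stays open. Whether mast cells were more abundant in the knockout ovaries stays open: 5 of the 8 markers other than Cpa3, Mcpt4, Tpsb2, Fcer1a, Mrgprb1 and Cma1, were higher in both knockout arrays than in both wild types, against 1.36 in random lists (percentile 99.8), but all 5 had means under the floor. Hdc, the only other marker with a mean at the floor, was not, at 6.43 and 5.79 in the knockouts against 5.30 in the untreated and 6.70 in the eCG-treated wild type. For the other genes, loss of aromatase itself and differences between animals were not tested.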
